A study of Bos taurus with 6 samples.

How the data were processed

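RNA of cultured bovine ovarian stromal fibroblasts, 3 samples from normal ovary and 3 from ovarian tumor, was labelled with biotin and hybridised to microarrays. Samples were grouped by their titles, which also gave the replicate numbers. The deposited values are log2 expression values made with RMA, per the submitters' processing notes; RMA corrects background, normalizes arrays by quantiles and summarises probes, and its version and software are not given in the sources used here. Per the labels' protocols, the RNA was prepared with a kit for 3' amplification in 1 cycle, while the numeric identifiers resemble those of a whole-transcript array, so which part of each transcript was read stays unknown here. The table held 24415 rows, taken as probe sets, in 6 samples, with values from 0.4 to 13.37 given to 2 decimals, and 164 rows repeated the 6 values of another. Control rows could not be told apart in the table and stayed in. Scanner intensities, detection calls, scan dates and slides were not used here, so no batch could be examined. For arrays the number of samples limits the precision.

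Genes were named through the platform annotation, which can be old. Of the probe sets, 18457 had 1 gene symbol, 688 had several and 5270 were unnamed here. Entrez identifiers of 17996 matched the RefSeq gene table of assembly ARS-UCD2.0, and 0 symbols needed an update. This table served for names and for which genes neighbour each other, and no coordinates are given. No gene was named from a probe set with several symbols, which leaves out ACTA2 and STAR. Each of 18010 genes was represented by its probe set with the highest mean over the 6 samples (401 genes had over 1).

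Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariates), on the log2 values with no further normalization or filter, with Benjamini-Hochberg adjustment over all probe sets or all genes and a threshold of 0.05. Errors beside log2 fold changes are standard errors, and those beside group levels are standard deviations. Fold changes are tumor minus normal.

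The main test, the alternatives, the rule for named genes and 34 gene lists were fixed before the data were examined. The lists came from textbook knowledge. They cover collagens, matrix glycoproteins, matrix proteases, cancer-associated fibroblast markers, contractile genes, steroidogenesis, granulosa markers, ovarian transcription factors and receptors, cholesterol synthesis, mitosis, DNA replication, p53 targets, interferon-stimulated genes, inflammatory genes, TGF-beta, Wnt, insulin-like growth factors, growth factors, glycolysis and hypoxia, oxidative phosphorylation, ribosomal proteins, stress responses, heat shock, antioxidants, antigen presentation, complement, lipid storage, lysosome, Hippo-YAP and immediate early genes, transition regulators, and markers of leukocytes, endothelium, pericytes and epithelium. Some genes are in more than 1 list. Each list was set against all other genes with camera (preset correlation 0.01), adjusted over the 34 lists, and again with an estimated correlation and with fry. Named genes were the 10 with the largest rise and the 10 with the largest fall among called genes whose groups did not overlap, up to 4 called members of each list with the largest change, and 25 genes fixed by name, of which 23 were measured; the report gives some of these. Some list members whose fold change the report leaves out lost their call with 1 sample left out. They are CA9, SLC2A3, IFI27, MYH11, LOXL4, PTGES, STC1, MCM10, RFC2, LMNB1, BTG2, NOTCH3, SC5D, NSDHL, GCLC, PPARG, PROX1 and ACSL3.

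The fit was tested on simulated data for the 18010 genes of the tumor and normal comparison, with 50 genes changed at each size. It recovered 10% at a log2 change of 0.5, 64% at 1, 86% at 2 and 100% at 3, with 5 false calls, and made 0 calls where nothing was changed. Far fewer genes were changed than the 3242 called in the data, so the recovery there may differ. Noise was drawn for each gene on its own, so the false calls do not cover genes that vary together.

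Alternatives were quantile normalization, median centring, leaving out the dimmest probe sets, a mean-variance trend, a robust prior, array weights, a replicate block, other thresholds, the mean of a gene's probe sets, other set tests, and leaving out each sample in turn. A filter at the 95th percentile of 717 olfactory receptor probe sets (3.54) was added after seeing the data.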

Results

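Messenger RNA was measured by microarray in cultured stromal fibroblasts from the bovine ovary, the connective tissue cells that surround the follicles. The labels gave 3 samples of cells from normal ovary and 3 from ovarian tumor, grown without any specific treatment, and did not name the type of tumor. The comparison of tumor with normal cells asked which transcripts differed between these cultures. Each sample had 24415 log2 expression values, with sample medians from 4.45 to 4.55, and the number of samples limited the precision. Pearson correlations over all values were 0.9832 to 0.9906 between normal samples, 0.9882 to 0.9909 between tumor samples and 0.9541 to 0.9737 between the groups. The first principal component held 64.93% of the variance and separated the groups. The second held 12.84% and spread the normal samples, with scores of 34.15 for normal 1, 6.13 for normal 2 and -31.78 for normal 3.

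Tumor stromal cells had far more mRNA of several secreted and surface proteins than normal stromal cells. EFEMP1, the matrix glycoprotein fibulin-3, stood at 3.45 ± 0.19 in normal and 11.46 ± 0.35 in tumor cells (log2, SD, n = 3), a 257-fold rise (adjusted p = 3.04e-06, limma with Benjamini-Hochberg adjustment). ALPL, the tissue-nonspecific alkaline phosphatase, rose 92.4-fold, the growth factor IGF2 75.9-fold, and the protease inhibitor A2M 65.2-fold. In the other direction GABRB1, a subunit of the GABA-A receptor, fell from 8.16 ± 0.60 to 2.75 ± 0.18, HAS2, a hyaluronan synthase, from 7.91 ± 0.81 to 3.24 ± 0.05, and GREM1, a secreted antagonist of bone morphogenetic proteins, from 8.81 ± 0.48 to 4.26 ± 0.72. The dimmer group of EFEMP1, GABRB1 and HAS2 lay under 3.54, a level set by olfactory receptor genes as a guide to background, so these sizes are not exact. Of 37 mitotic genes 27 fell, and of 47 genes of oxidative phosphorylation 20 fell. Camera called both lists lower with a preset correlation, but not with the correlation taken from the data (adjusted p = 0.751 with an estimated correlation for each).

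Among 18010 genes, 3242 (18%) passed an adjusted p of 0.05 in limma, 1542 higher and 1700 lower in tumor cells. Of these, 1176 differed at least 2-fold and 272 at least 4-fold. In 3240 of the 3242 genes the samples of the groups did not overlap. Over all genes 35.7% had groups that did not overlap, where chance gives 10%. Over all probe sets, 3329 of 24415 passed. The gene count was 1765 without normal replicate 2, 1968 without tumor replicate 1 and 1887 without tumor replicate 2. The labels do not say that the samples came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

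The remaining genes with the largest rises were CLEC2D (log2 fold change 6.04 ± 0.28, SE), a C-type lectin; ASPN (5.64 ± 0.41), a small leucine-rich proteoglycan; FGL2 (5.27 ± 0.21), a fibrinogen-like protein; NDUFA4L2 (5.12 ± 1.03); CLDN1 (4.96 ± 0.38), a tight junction protein; and TNFSF18 (4.79 ± 0.35), a ligand of the tumor necrosis factor family. Their adjusted p ran from 1.99e-05 for FGL2 to 0.013 for NDUFA4L2. NDUFA4L2 varied widely among normal cells, at 7.03, 3.80 and 2.16, and its call was lost without normal replicate 2 (adjusted p = 0.0536). The remaining genes with the largest falls were GPX6 (-5.17 ± 0.45), a glutathione peroxidase; ADCY2 (-4.87 ± 0.30), an adenylyl cyclase; RADX (-4.67 ± 0.17); CDH6 (-4.64 ± 0.13), a cadherin; PRKCB (-4.53 ± 0.24), a protein kinase C; LRFN5 (-4.41 ± 0.14); and CYYR1 (-4.31 ± 0.25). The other probe set of GABRB1 differed by -0.67, so the size of its fall depended on the probe set. Olfactory receptor genes, which fibroblasts are not known to use, gave a guide to background, and 95% of their group means lay under 3.54. EFEMP1, CLEC2D and FGL2 were under that level in normal cells, and GABRB1, ADCY2, HAS2, RADX, CDH6, PRKCB, LRFN5 and CYYR1 were under it in tumor cells, so their folds understate the change if the dimmer group had no transcript. The same limit holds wherever a gene is said to lie under the olfactory receptor level.

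**Figure D1:**
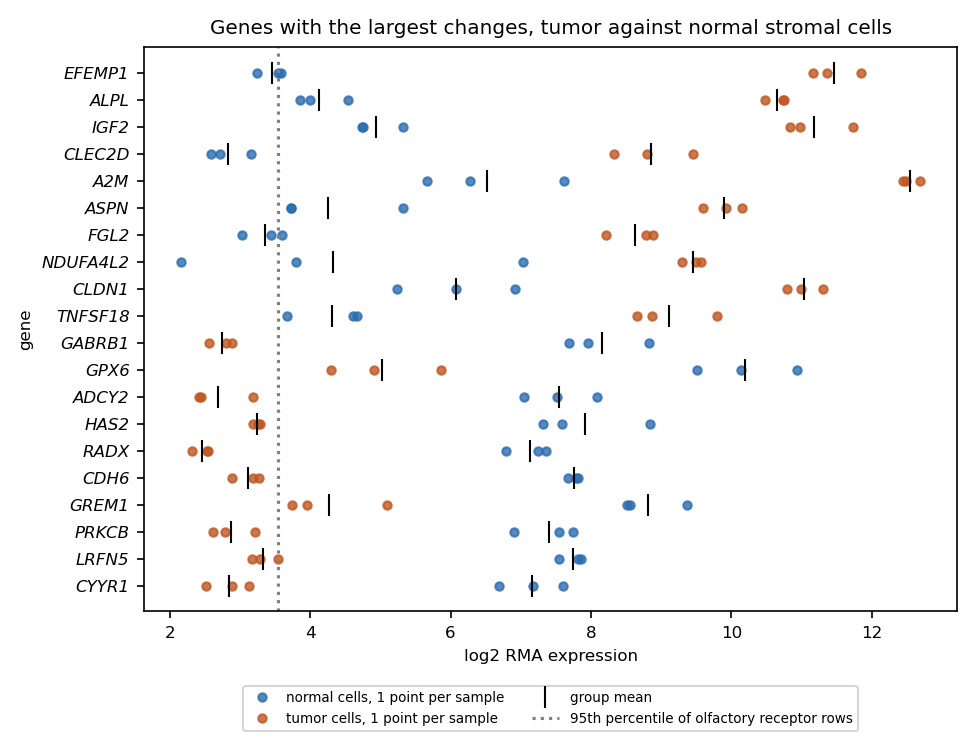
Log2 expression of the 10 genes with the largest rise and the 10 with the largest fall in tumor over normal stromal cells, with 1 point per sample, a bar at the group mean and a dotted line at the olfactory receptor level of 3.54. The 3 normal and 3 tumor samples did not overlap in any of them, and NDUFA4L2 had the widest spread among normal samples (SD 2.48).

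Matrix genes rose more often than they fell. Of 45 measured matrix glycoproteins and proteoglycans, 16 rose and 4 fell over all genes, and 21 rose and 6 fell when adjusted over the list alone. Without tumor replicate 1 or without tumor replicate 2, 10 rose. EFEMP1, ASPN and OGN (osteoglycin, 4.56 ± 0.32) rose, and HAS2 fell. The list was higher than other genes in camera (adjusted p = 0.003), but not with the correlation between its genes taken from the data (adjusted p = 0.751 with an estimated correlation). Of 25 collagens, 7 rose and 3 fell, and the counts were equal when adjusted over the list alone. The basement membrane chains COL4A5 (2.40 ± 0.31) and COL4A1 (1.97 ± 0.16) rose, and COL11A1 (-2.79 ± 0.12) and COL15A1 (-2.28 ± 0.40) fell. COL3A1 rose by 0.61 ± 0.14, a call lost without tumor replicate 1 or 2 (adjusted p = 0.0726 and 0.0815), while COL1A1, the main fibrillar chain, differed by 0.01 ± 0.11 (adjusted p = 0.977). The collagen list just passed (adjusted p = 0.0494 in camera; adjusted p = 0.758 with an estimated correlation) and was lost without normal replicate 1 or 3 or tumor replicate 1 or 2 (adjusted p = 0.0629, 0.103, 0.0735 and 0.0718), with 4 collagens that rose without tumor replicate 1 and 4 without tumor replicate 2. It was also lost with quantile normalization (adjusted p = 0.0912), the dimmest probe sets left out (0.0982), array weights (0.0693) and the olfactory receptor filter (0.101). Of 35 matrix proteases, inhibitors and cross-linkers, 7 rose and 4 fell, or 9 and 5 adjusted over the list alone, and camera did not call the list (adjusted p = 0.385; 0.0268 without normal replicate 1). The number that rose was 13 without normal replicate 1, 4 without normal replicate 3 and 3 without normal replicate 2, tumor replicate 1 or tumor replicate 2, and 2 fell without normal replicate 2, tumor replicate 2 or tumor replicate 3. SERPINF1 (3.58 ± 0.46), a serpin, and TIMP3 (1.92 ± 0.27), a metalloproteinase inhibitor, rose, and the urokinase gene PLAU fell (-2.31 ± 0.22). In normal cells EFEMP1, COL4A5 and SERPINF1, and in tumor cells HAS2, lay under the olfactory receptor level.

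Markers of activated fibroblasts changed in both directions. Of 25 cancer-associated fibroblast markers, 4 rose and 3 fell over all genes, and 10 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.41). S100A4, a calcium-binding protein, rose by 3.46 ± 0.36, and INHBA, the activin subunit, by 2.05 ± 0.34. GREM1 fell, as did WNT5A (-1.94 ± 0.20). FAP differed by 1.70 ± 0.82 (adjusted p = 0.205), at 7.62, 6.44 and 4.37 in normal and 8.88, 7.93 and 6.73 in tumor samples. THY1 differed by 1.35 ± 0.41 (adjusted p = 0.0608; 0.00957 without tumor replicate 3 and 0.0156 with array weights). Both FAP and THY1 passed with the replicate block. PDGFRB differed by 0.39 ± 0.19 (adjusted p = 0.205) and the mesenchymal filament gene VIM by -0.29 ± 0.11 (adjusted p = 0.117; 0.0369 with a mean-variance trend). PDGFRA rose by 0.89 ± 0.20, a call lost without tumor replicate 1 or 2 (adjusted p = 0.0708 and 0.0713). Of 27 contractile genes, 6 rose and 8 fell, or 7 and 8 adjusted over the list alone (camera adjusted p = 0.653, direction down, as for the median of -0.07, with a mean of 0.14). Of these, 3 rose without normal replicate 1, normal replicate 2 or tumor replicate 2, and 5 fell without normal replicate 2. PDLIM3 (4.40 ± 0.40) and FHL1 (1.56 ± 0.17) rose and TPM2, a tropomyosin, fell (-1.27 ± 0.16). Of 28 regulators and junction genes of the epithelial-mesenchymal transition, 8 rose and 7 fell, or 9 and 10 adjusted over the list alone (camera adjusted p = 0.908, direction down, with a median of 0.01 and a mean of -0.12). The number that rose was 4 without normal replicate 2 and 5 without tumor replicate 2. The integrins ITGA2 (-4.03 ± 0.26) and ITGA6 (-3.93 ± 0.18) and the cadherin CDH2 (-2.41 ± 0.18) fell, with ITGA2 under the olfactory receptor level in tumor cells.

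Hormone receptors and gonadal transcription factors changed in both directions. Of 22 measured, 7 rose and 5 fell, or 8 and 5 adjusted over the list alone (camera adjusted p = 0.769, direction up, with a median of -0.003 and a mean of -0.13). The estrogen receptor ESR1 rose by 2.81 ± 0.22. EMX2 (-3.05 ± 0.18), TCF21 (-2.53 ± 0.26), GATA4 (-2.45 ± 0.24) and FOXL2 (-1.69 ± 0.15) fell, as did the progesterone receptor PGR (-1.96 ± 0.19), whose other probe set differed by -0.12. Of 23 steroidogenesis and theca genes, 6 rose and 1 fell, or 8 and 1 adjusted over the list alone (camera adjusted p = 0.0323; adjusted p = 0.751 with an estimated correlation). This call was lost without normal replicate 3 or tumor replicate 2 (adjusted p = 0.103 and 0.0543) and with camera on ranks (adjusted p = 0.0701). The nuclear receptor NR5A2 (3.19 ± 0.19) and HSD3B1 (2.18 ± 0.21), a hydroxysteroid dehydrogenase with near-identical copies and so uncertain, rose. CYP17A1, the enzyme of androgen synthesis, rose by 2.31 ± 0.62 but lay at 8.20, 6.54 and 5.28 in the tumor samples, and its call was lost without any 1 of the 3 normal samples or tumor replicate 2 (adjusted p = 0.0766 to 0.0987). CYP11A1 differed by 1.12 ± 0.42 (adjusted p = 0.11; 0.0268 without tumor replicate 3) and the aromatase gene CYP19A1 by 0.06 ± 0.11 (adjusted p = 0.798). Of 24 granulosa and Sertoli cell markers, 5 rose and 4 fell, or 6 and 4 adjusted over the list alone (camera adjusted p = 0.908, direction up, with a median of 0.06 and a mean of -0.01). Of these, 3 rose without normal replicate 2 or 3 or tumor replicate 1 or 2. AMH differed by 0.54 ± 0.16 (adjusted p = 0.0569; 0.034 with array weights, 0.0467 with the dimmest probe sets left out and 0.0458 with the olfactory receptor filter) and INHA by -0.19 ± 0.14 (adjusted p = 0.441). NR5A2 in normal cells, FOXL2 and PGR in tumor cells, and CYP19A1 and INHA in both lay under the olfactory receptor level.

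Of 37 mitotic genes, 27 fell and 0 rose over all genes in limma, and 34 fell adjusted over the list alone, with a median of -1.27 (camera adjusted p = 7.18e-14; adjusted p = 0.751 with an estimated correlation). The number that fell was 11 without tumor replicate 1 and 14 without tumor replicate 3, and the list passed camera in each of the 6 fits that left out 1 sample (adjusted p of 5.26e-12 or less). CENPA (-2.03 ± 0.39) and CENPE (-1.85 ± 0.35), of the centromere and kinetochore, CDC20 (-1.84 ± 0.31), an activator of the anaphase-promoting complex, and the kinase PLK1 (-1.81 ± 0.24) fell. MKI67 differed by -1.20 ± 0.38 (adjusted p = 0.0655; 0.0411 without normal replicate 1 and 0.0391 with array weights). Per-sample means of the list were 7.15, 7.25 and 8.13 in normal and 5.84, 6.58 and 6.42 in tumor cells. Of 37 genes of DNA replication, 1 rose and 1 fell over all genes and 0 in either direction adjusted over the list alone, with 0.019 as the camera adjusted p and a direction down (adjusted p = 0.875 with an estimated correlation). That call was lost without normal replicate 3 (adjusted p = 0.941) or tumor replicate 1 (adjusted p = 0.178), and with array weights (0.672), the dimmest probe sets left out (0.0551) and the olfactory receptor filter (0.0629). Leaving out 1 sample gave 0 to 2 that rose (2 without normal replicate 3, 0 without any other) and 0 that fell in limma (1 without normal replicate 1). Of 24 p53 targets and senescence genes, 11 rose and 4 fell, or 14 and 4 adjusted over the list alone (camera adjusted p = 0.0184; adjusted p = 0.751 with an estimated correlation). The number that rose was 6 without normal replicate 2 or tumor replicate 2 and 5 without tumor replicate 3, and 1 or 2 fell without any sample but normal replicate 3. The cell cycle inhibitor CDKN1A (1.47 ± 0.22) and ZMAT3 (1.30 ± 0.22) rose, and CDKN2A, which encodes another inhibitor, fell (-0.91 ± 0.12).

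**Figure D2:**
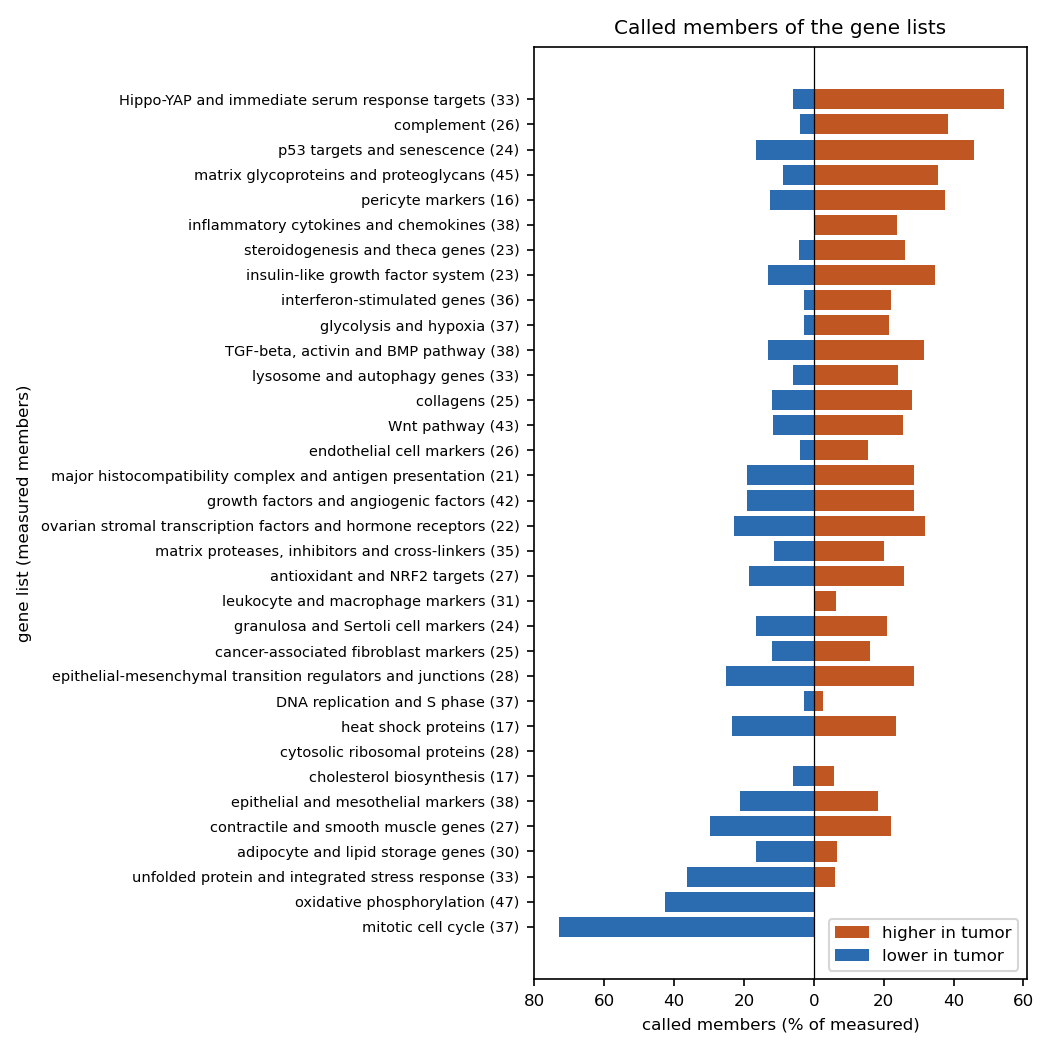
Share of the measured members of each of the 34 gene lists that were higher or lower in tumor cells at an adjusted p of 0.05 (limma, over all genes). Mitotic genes (27 of 37 lower) and oxidative phosphorylation (20 of 47 lower) had called members in the lower direction only.

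Of 47 oxidative phosphorylation genes, 20 fell and 0 rose over all genes in limma, and 24 fell and 1 rose adjusted over the list alone, with a median of -0.41 (camera adjusted p = 2.8e-08; adjusted p = 0.751 with an estimated correlation). The number that fell was 6 without normal replicate 2, 10 without normal replicate 3, 9 without tumor replicate 1 and 8 without tumor replicate 2. With the preset correlation of 0.01, the list passed camera in each of the 6 fits that left out 1 sample (adjusted p of 1.47e-06 or less). The estimated correlation was 0.449, so these p-values too are too small to show that the result is stable. ATP5MC1 (-1.16 ± 0.22), of the ATP synthase, NDUFA4 (-1.02 ± 0.14) and CYC1 (-0.95 ± 0.14), cytochrome c1, fell. Of 37 glycolysis and hypoxia genes, 8 rose and 1 fell, or 9 and 2 adjusted over the list alone (camera adjusted p = 0.0261; adjusted p = 0.875 with an estimated correlation). PFKFB3, a regulator of glycolysis, rose by 2.25 ± 0.25, and the neuronal enolase ENO2 fell (-1.80 ± 0.20). Sample means of this list were 8.83, 8.21 and 7.64 in normal and 8.73, 8.78 and 8.83 in tumor cells, so normal 1 stood level with the tumor samples. Its call was lost without normal replicate 3 (adjusted p = 0.263) or tumor replicate 3 (adjusted p = 0.0962), and without normal replicate 1 the number of members that rose was 16 (adjusted p = 4.27e-06). It was 3 without normal replicate 2, tumor replicate 2 or tumor replicate 3, 4 without tumor replicate 1 and 5 without normal replicate 3. Of 33 lysosome and autophagy genes, 8 rose and 2 fell, or 11 and 4 adjusted over the list alone (camera adjusted p = 0.0413; adjusted p = 0.787 with an estimated correlation), a call lost without normal replicate 3 or tumor replicate 3 (adjusted p = 0.103 and 0.275). Of these, 3 rose without normal replicate 2, tumor replicate 1 or tumor replicate 2, 4 without tumor replicate 3 and 5 without normal replicate 3. The number that fell was 4 without tumor replicate 3 and 1 without normal replicate 2, tumor replicate 1 or tumor replicate 2. The cathepsins CTSS (2.41 ± 0.21) and CTSF (1.57 ± 0.22) rose. Of 30 adipocyte and lipid storage genes, 2 rose and 5 fell, the same numbers as adjusted over the list alone (camera adjusted p = 0.991, direction down, with a median of 0.05 and a mean of -0.07), among them FABP3 (-3.06 ± 0.45), a fatty acid binding protein. The number that rose was 4 without normal replicate 1, 0 without normal replicate 2 and 1 without normal replicate 3 or tumor replicate 1 or 2, and 3 fell without normal replicate 2 or tumor replicate 1. Of 17 cholesterol synthesis genes, 1 rose and 1 fell by both adjustments, over all genes and adjusted over the list alone (camera adjusted p = 0.653). Of these, 3 rose without normal replicate 1 and 0 without normal replicate 2 or tumor replicate 2, and 0 fell without tumor replicate 1 or 3. Of 28 cytosolic ribosomal protein genes, 0 were called in limma by either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.653); RPL38 differed by -0.42 ± 0.15 (adjusted p = 0.0926; 0.044 with array weights). Without normal replicate 1, 1 fell.

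Of 33 targets of Hippo-YAP signaling and the immediate serum response, 18 rose and 2 fell, or 20 and 2 adjusted over the list alone, with a median of 0.83 (camera adjusted p = 9.96e-07; adjusted p = 0.751 with an estimated correlation). Without normal replicate 2 or tumor replicate 3, 11 rose, and the number that fell was 0 without normal replicate 2 and 1 without normal replicate 3, tumor replicate 2 or tumor replicate 3. The transcription factor genes FOSB (3.55 ± 0.34), FOS (2.27 ± 0.18) and KLF4 (2.21 ± 0.23) rose. NR4A1 rose by 2.16 ± 0.58, a call lost when any sample but normal replicate 1 was left out (adjusted p = 0.0514 to 0.113) and with a robust prior (0.0519). Of 33 genes of the unfolded protein and integrated stress response, 12 fell and 2 rose, or 16 and 2 adjusted over the list alone (camera adjusted p = 1.02e-05, direction down; adjusted p = 0.751 with an estimated correlation). CRELD2 (-1.43 ± 0.20), of the endoplasmic reticulum, and PSAT1 (-1.37 ± 0.25), of serine synthesis, fell, and ATF3 (1.79 ± 0.31) and PPP1R15A (1.42 ± 0.21) rose. Of 17 heat shock genes, 4 rose and 4 fell, or 4 and 6 adjusted over the list alone (camera adjusted p = 0.769, direction down, with a median of -0.20 and a mean of 0.09). Of these, 2 fell without normal replicate 2 or tumor replicate 1 or 2. The small heat shock genes CRYAB (2.25 ± 0.23) and HSPB6 (2.12 ± 0.22) rose and CHORDC1 (-1.32 ± 0.20) fell. Of 27 antioxidant genes, 7 rose and 5 fell, or 8 and 7 adjusted over the list alone (camera adjusted p = 0.653, direction up, with a median of -0.05 and a mean of 0.22), with a rise of GPX3 (2.81 ± 0.24), the plasma glutathione peroxidase. Without normal replicate 2, 4 rose, and the number that fell was 2 without normal replicate 2 or tumor replicate 2 and 3 without tumor replicate 1.

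Of 26 complement genes, 10 rose and 1 fell, or 13 and 2 adjusted over the list alone (camera adjusted p = 0.00664; adjusted p = 0.751 with an estimated correlation). Without normal replicate 2, 6 rose, and without normal replicate 3, 3 fell. C1S (3.19 ± 0.32) and C1R (2.55 ± 0.40), proteases of the classical pathway, CFB (2.50 ± 0.24), of the alternative pathway, and the inhibitor SERPING1 (2.65 ± 0.36) rose. Of 38 inflammatory cytokines and chemokines, 9 rose and 0 fell over all genes in limma, and 11 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.017; adjusted p = 0.758 with an estimated correlation). The adhesion gene VCAM1 (4.64 ± 0.49), the hyaluronan-binding TNFAIP6 (4.54 ± 0.17) and PTGS2 (2.55 ± 0.39), of prostaglandin synthesis, rose, and the call of the list was lost without normal replicate 3 (adjusted p = 0.0854). Without tumor replicate 2, 5 of these genes rose and 1 fell. Of 36 interferon-stimulated genes, 8 rose and 1 fell by both adjustments, over all genes and adjusted over the list alone (camera adjusted p = 0.0211; adjusted p = 0.751 with an estimated correlation), a call lost without normal replicate 3 or tumor replicate 3 (adjusted p = 0.0809 and 0.053) and with array weights (adjusted p = 0.0666). Without normal replicate 2 or tumor replicate 1, 5 rose, and 0 fell in limma without normal replicate 2. IFI6 rose by 2.78 ± 0.54, at 9.19, 8.77 and 11.10 in the tumor samples, and IFIH1, a sensor of viral RNA, by 1.94 ± 0.19. Sample means of the interferon list were 4.61, 4.60 and 4.45 in normal and 4.89, 4.81 and 5.30 in tumor cells, highest in tumor 3. Of 21 genes of antigen presentation, 6 rose and 4 fell by both adjustments, over all genes and adjusted over the list alone (camera adjusted p = 0.503, direction up, with a median of -0.02 and a mean of 0.19). Of these, 3 rose without normal replicate 2 or tumor replicate 2. ERAP2, a peptidase that trims antigens, fell (-1.27 ± 0.19). The 2 probe sets of the class I gene BOLA differed by -2.73 and 1.36, and its direction is uncertain, as near-identical copies share probes. VCAM1, TNFAIP6, C1R and IFIH1 lay under the olfactory receptor level in normal cells.

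**Figure D3:**
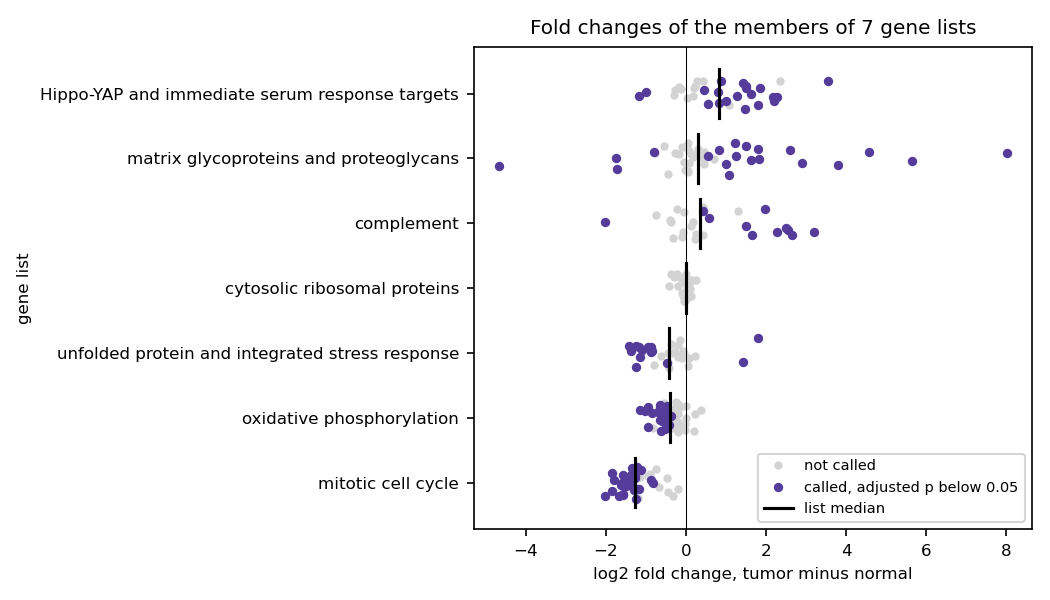
Log2 fold change of each measured member of 7 of the gene lists, chosen after their values were seen, in tumor over normal cells, with 1 point per gene and a bar at the list median. Mitotic genes lay around a median of -1.27 and immediate early and Hippo-YAP targets around 0.83.

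Growth factor genes changed in both directions. Of 42 growth and angiogenic factors and their receptors, 12 rose and 8 fell, or 16 and 8 adjusted over the list alone (camera adjusted p = 0.0854; 0.0228 without normal replicate 1). FGF10 (4.19 ± 0.16) and VEGFD (3.24 ± 0.41), a lymphangiogenic factor, rose, and FGF5 (-2.45 ± 0.34) and the receptor FLT1 (-2.24 ± 0.25) fell. FGF10 and VEGFD in normal cells and FGF5 in tumor cells lay under the olfactory receptor level. Of 23 genes of the insulin-like growth factor system, 8 rose and 3 fell, or 9 and 4 adjusted over the list alone (camera adjusted p = 0.323). The number that rose was 3 without normal replicate 2 or tumor replicate 2 and 5 without normal replicate 3 or tumor replicate 1. IGF2 rose, and IGFBP2 (-2.62 ± 0.14), a binding protein, and IGF2R (-1.74 ± 0.11), the receptor that clears IGF2, fell. Of 38 genes of the TGF-beta, activin and BMP pathway, 12 rose and 5 fell, or 14 and 7 adjusted over the list alone (camera adjusted p = 0.385). Only 7 rose without normal replicate 2 or tumor replicate 2. BMP6 (3.06 ± 0.23) and the co-receptor TGFBR3 (2.71 ± 0.31) rose, and BMP2 (-2.92 ± 0.21) fell. Of 43 Wnt pathway genes, 11 rose and 5 fell by both adjustments, over all genes and adjusted over the list alone (camera adjusted p = 0.36). Of these, 3 fell without normal replicate 2. RSPO3 (3.34 ± 0.19), an enhancer of Wnt signaling, and SFRP1 (2.95 ± 0.23), a secreted antagonist, rose.

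Markers of other cell types gave a mixed picture. Of 31 leukocyte and macrophage markers, 2 rose and 0 fell in limma by both adjustments, over all genes and adjusted over the list alone (camera adjusted p = 0.311). These were LAPTM5 (2.43 ± 0.19) and CD68 (1.15 ± 0.17), both of the lysosome, while the pan-leukocyte gene PTPRC was at 2.37 ± 0.11 in normal and 2.32 ± 0.12 in tumor cells (SD, n = 3), under the olfactory receptor level, as LAPTM5 was in normal cells. Of 26 endothelial markers, 4 rose and 1 fell by both adjustments, over all genes and adjusted over the list alone (camera adjusted p = 0.385), with a rise of EMCN (1.69 ± 0.24) and PECAM1 at -0.35 ± 0.15 (adjusted p = 0.17; 0.0196 with array weights). Of these markers, 2 rose without normal replicate 2. Of 16 pericyte markers, 6 rose and 2 fell, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.0494; adjusted p = 0.758 with an estimated correlation). RGS4 (1.92 ± 0.29) and HEYL (1.46 ± 0.17) rose, and the call of the list was lost without normal replicate 2 or 3 or tumor replicate 1 or 2 (adjusted p = 0.073, 0.0854, 0.0735 and 0.0663), with quantile normalization (0.0829) and with camera on ranks (0.0687). Without normal replicate 2, 3 of these genes rose and 1 fell. Of 38 epithelial and mesothelial markers, 7 rose and 8 fell by both adjustments, over all genes and adjusted over the list alone (camera adjusted p = 0.503). The number that rose was 3 without normal replicate 2 or tumor replicate 1 and 4 without normal replicate 3 or tumor replicate 2. The desmosomal cadherins DSG2 (-3.28 ± 0.22) and DSC2 (-2.89 ± 0.32) and the keratin KRT18 (-2.78 ± 0.46) fell while CLDN1 rose. DSG2 and PECAM1 lay under the olfactory receptor level in tumor cells. KRT8 fell by 1.06, a call lost when any sample but normal replicate 3 was left out (adjusted p = 0.08 to 0.135).

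Over the 34 lists, camera with a preset correlation of 0.01 called 15, of which 11 were higher and 4 lower in tumor cells, and 7 were called without normal replicate 3. With an estimated correlation camera called 0 (1 at an unadjusted p under 0.05), and the directional test of fry, which does not compare a list with other genes, called 0 (13 at an unadjusted p under 0.05).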

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

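The olfactory receptor filter was chosen after the data were seen and gave 3811 probe sets, 3497 genes and 13 lists. Counts of probe sets, genes and lists stayed within 1.5 times of 3329, 3242 and 15, except as follows. Array weights called 5054 genes. A fold of at least 2 left 1307 probe sets and 1176 genes, and an adjusted p under 0.01 left 1151 and 1297, fewer by construction. An estimated correlation in camera called 0 lists (1 at an unadjusted p under 0.05), and fry called 0 (13 at an unadjusted p under 0.05, 32 by its test for change in either direction). Leaving out 1 sample gave 1594 to 3202 probe sets, 1765 to 3226 genes and 7 to 16 lists, with fewer samples in each fit. Deviations of same-numbered samples correlated at r of 0.052, -0.056 and 0.065, so no pairing by number was seen. Not every sample correlated best with its own number. With 3 samples per group these values cannot exclude a pairing. The replicate block gave 2764 probe sets, 2895 genes and 14 lists, with the lysosome list at an adjusted p of 0.0501. Under the block, adjusted p crossed the threshold upward for ACSL3 (0.0571), CYP17A1 (0.0541), KRT8 (0.061), MYH11 (0.0679), NR4A1 (0.0527) and RFC2 (0.0839), and downward for AMH (0.0378), FAP (0.00889), MKI67 (0.0218) and THY1 (0.028). Leaving out probe sets marked for cross-hybridisation was not run, as the identifiers carry no such marks.

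Of 135 called named genes, 110 stayed past the threshold in every setting counted here and 1 reversed. The other limits on fold and adjusted p were not counted among these settings. The reversed gene was BOLA, at -0.69 as the mean of its probe sets, which differ in direction. Among results not called, COL1A1 was -0.04, -0.01 and -0.06 with quantile normalization, centring and weights, and -0.04 to 0.06 with 1 sample left out, and PTPRC -0.11 to 0.01. List directions turned, all far from the threshold (adjusted p), for granulosa markers (0.868 with quantile normalization, 0.637 with fry), heat shock (0.712 with fry), transition regulators (0.97, 0.88, 0.861 and 0.959 with the dimmest probe sets left out, weights, ranks and the olfactory filter) and lipid storage (0.868, 0.993, 0.89, 0.822, 0.735 and 0.979 with quantile normalization, the dimmest probe sets left out, weights, the block, ranks and the olfactory filter). With 1 sample left out, directions turned for these, contractile genes and cholesterol synthesis. Over all 6 such fits, turned or not, adjusted p ran from 0.719 to 0.984, 0.441 to 0.906, 0.766 to 0.926, 0.571 to 0.981, 0.257 to 0.87 and 0.0585 to 0.947. The fits that turned were those without normal replicate 3 (granulosa markers, 0.984; heat shock, 0.842; contractile genes, 0.777; cholesterol synthesis, 0.748), tumor replicate 2 (granulosa markers, lipid storage, both 0.981; cholesterol synthesis, 0.947), tumor replicate 3 (granulosa markers, 0.95), normal replicate 1 (transition regulators, 0.781; lipid storage, 0.571) and tumor replicate 1 (transition regulators, 0.926). Apart from the constructions named, the cause was not tested. Signal over background limits the dimmer genes: 71.1% lay above the olfactory receptor level in either group.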

Other observations

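The tests of chaperones, of the ratio of epithelial genes and of homeobox genes, and the families below, were chosen after the result was seen. HOX genes are homeobox genes that mark position along the body axis. Of 26 above the olfactory receptor level, 7 rose and 3 fell in tumor cells and 16 did not pass (limma, adjusted over all genes). Among all genes above that level, 24.5% were called, and the shares were not compared by a test. HOXB8 (log2 fold change 2.82 ± 0.21), HOXB3 (1.87 ± 0.20) and HOXB4 (1.83 ± 0.18) were higher, and HOXD11 (-1.23 ± 0.22), HOXC8 (-1.10 ± 0.14) and HOXC5 (-1.09 ± 0.18) lower, with HOXD11 and HOXC5 under the olfactory receptor level in tumor cells. Their median absolute change of 0.45 lay at the 99.6 percentile of 10000 lists matched on mean level, whose median was 0.23. These genes were singled out because of their changes, so that percentile describes the observation and does not test it. That the cultures may hold stromal cells of different positional identity is a hypothesis these data leave open, as is a change of HOX genes with the tumor itself.

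Genes were also grouped by the root of their symbol into 147 families. Of genes of the mitochondrial ribosome, 11 of 27 MRPS genes and 12 of 47 MRPL genes were called lower and 0 higher in limma. Among all genes above background, 24.5% were called in either direction. A test of calls in either direction against that share did not pass (Fisher's exact test, p = 0.0698 and 0.866, adjusted p = 0.485 and 1). It leaves out direction, so it cannot tell whether falls were more frequent than in other genes. Camera called both families lower with the preset correlation (camera adjusted p = 4e-06 and 1.55e-05), but not with an estimated correlation (camera adjusted p = 0.877 for both). The lowest p for the share of calls was that of MIR (9 of 147 higher, 4 lower) and ZNF (20 of 222 higher, 6 lower). Both had fewer calls than other genes (Fisher's exact test, adjusted p = 0.000141 for each). Families were not matched on signal level, so these counts do not set them apart from genes of like signal. Phosphodiesterase genes had more calls (8 of 19 higher, 4 lower, adjusted p = 0.0194), and camera did not call them (adjusted p = 0.443; adjusted p = 0.877 with an estimated correlation).

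The mitotic list had a median of -1.27 in tumor over normal cells (adjusted p = 0.751 with an estimated correlation). Leaving out any 1 sample moved this to between -1.47 and -0.96, the latter without normal replicate 3, which argues against 1 sample as the cause. Of 10000 lists matched on mean level, 0 reached -1.27, with medians from -0.38 to 0.24, which argues against a bias with brightness. The matched genes were drawn singly and do not vary together as mitotic genes do, so this count is not a p-value. Crowding or low oxygen of single cultures stays open: within the groups, the mean of the hypoxia list went with that of the mitotic list at r = -0.69 (exact permutation p = 0.361) and rho = -0.26 (exact permutation p = 0.722) over 6 samples, and r was 0.71 without normal 1 and normal 3, so the relation rests on those samples. A difference in growth between tumor and normal cells may also account for it and was not tested.

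The list of Hippo-YAP and immediate serum response targets had a median of 0.83 (adjusted p = 0.751 with an estimated correlation), and 0.65 or more with any 1 sample left out. The values with 1 sample left out argue against 1 sample as the cause. Of 10000 matched lists, also drawn gene by gene, 0 reached 0.83, with medians from -0.36 to 0.35, which argues against a bias with brightness. Stress of handling could also raise these genes. Of the chaperones set for this test, HSPA1A, DNAJA1 and HSP90AA1 were not measured. The 5 measured ones, HSPA8, HSPH1, DNAJB1, HSPE1 and HSPB1, had a median change of -0.2, and 4 of the 5 had 95% intervals under 0.4. Among them was HSPH1, the only called one, which fell (-1.09, interval -1.62 to -0.56, adjusted p = 0.015 in limma). In the wider heat shock list of 17 genes, 4 rose, among them CRYAB and HSPB6, and 4 fell, so these 5 do not speak for all stress genes. The interval of DNAJB1 (0.26, -0.05 to 0.56) reached past 0.4, so this cannot be told apart from a difference of the cells.

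Of the epithelial list 7 markers rose and 8 fell, and camera did not call the list (adjusted p = 0.503). Those that fell were KRT8, KRT18, KRT19, DSC2, DSG2, PKP2, PAX8 and BNC1, taken here because they fell. A varying share of epithelial cells in the normal cultures would keep the excess of these genes over the stromal level in 1 ratio between samples. The tumor mean was taken as that stromal level, which was not tested. The log2 ratio of this excess in normal 1 over normal 3 differed by 3.04 between 4 genes with a normal mean of at least 6. This limit was set after the range of 4 over all 8 called genes was seen. The ratio first set for this test, of the highest over the lowest normal sample, ran from 0.36 for DSC2 to 2.53 for KRT18 over the 4 genes. For normal 1 over normal 3, KRT18 (1.99) was higher in normal 1 and DSG2 (-1.05) in normal 3, which argues against 1 admixture behind both. KRT8 (2.95), left out by the limit, went with KRT18, so a varying share of cells with KRT8 and KRT18 stays open. Regulation within the stromal cells may differ between the groups and was not tested.

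Changes of adjacent genes with unlike names correlated at 0.075 across genes, which are not independent replicates, above all 1000 reshuffles (-0.027 to 0.027). Gains or losses of chromosome segments could give this, but so could regulation or hybridisation shared by neighbours: the difference between normal 1 and normal 3 also gave 0.075 to 3 decimals, and the other 5 differences within a group 0.028 to 0.058. The hypotheses cannot be told apart, and 1 of 30 chromosome medians lay beyond the reshuffled range. Of 468 windows of 50 genes, 1 lay beyond the 1st and 99th percentiles of reshuffled extremes, at a median of -0.33 where the limit was also -0.33 to 2 decimals.

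The 6 samples can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 3329 probe sets and 3242 genes in limma, and the highest of the others called 0 of each (1127 probe sets and 782 genes at an unadjusted p under 0.05), so 1 of the 10 splits gave as many. For lists, the real split called 15 and the highest other, which set normal 1, tumor 1 and tumor 2 against the rest, called 16, so 2 of 10 gave as many.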
